A study of Homo sapiens with 16 samples.

How the data were processed

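RNA from 16 xenograft tumours was sequenced as stranded mRNA libraries, per the labels' protocols. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0, checked with FastQC 0.11.8, aligned with STAR 2.6.1d, counted per gene with featureCounts 1.5.1 and compared with DESeq2 1.22.2. The notes name the genome builds GRCh38, GRCm38 and mm10. How mouse reads were handled, the strand setting of the counting and the annotation release are not given in the sources used here. The values as deposited are raw read counts per gene, in a table of 58302 human gene IDs and 16 tumours, with 2 blank lines holding 0 counts. Total counts per tumour ran from 22799938 to 49192818. No pair of tumours had counts close enough to be copies of 1 library (chi-square per gene of 14.7 to 141 over pairs).

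Gene IDs were matched to symbols without their version: 57532 had a current symbol, 507 more a name in GENCODE release 29, and 263 no name. Coordinates are those of GENCODE 29 on GRCh38. Reads of overlapping or antisense genes, paralogs and pseudogenes cannot be told apart in a table of counts per gene. This concerns KBTBD11-OT1 and BBOX1-AS1, the HLA genes, ribosomal protein genes with processed pseudogenes, and mitochondrial genes with nuclear copies.

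Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr (min.count 10, min.total.count 15), which left 20118 genes, and quasi-likelihood fits with robust estimation of all 16 tumours as 4 groups, with 12 residual degrees of freedom and a common biological coefficient of variation of 0.220. There were 7 comparisons: each of the 3 treated groups against control, GANT61+RITA against RITA and against GANT61, RITA against GANT61, and the interaction. P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and all tests were two-sided. Log2-CPM used a prior count of 2, and CPM values are scaled by TMM-adjusted totals, over all or over tested genes, the latter holding at least 99.86% of counts. No paired analysis was possible because the replicate numbers pair no tumours, and the labels give no batch.

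Of 29 gene lists, 27 were tested with camera of limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over the 27 lists of a comparison. The blood cell and the fat and skin lists had fewer than 5 tested members, and 4 list symbols were not found. Each list was also tested with an estimated correlation, with fry and, as a test added later, for comparisons of 2 groups with an exact permutation of the mean log2-CPM over 70 assignments of 8 tumours. fry asks whether a list's genes move one way on balance and compares them with no other genes. The comparisons, the lists, the tests apart from that permutation, the first set of alternatives and the rule for named genes were written before the data were examined. That rule named genes past the threshold in non-overlapping groups, or, where none passed, the 5 genes with the smallest unadjusted p, then up to 4 members of each list with the smallest p, and in every comparison GLI1, PTCH1, HHIP, CDKN1A, MDM2, MKI67 and TP53. From these, the genes printed were picked to represent the lists that passed and the Hedgehog and p53 lists.

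The alternatives were DESeq2 size factors or upper-quartile scaling in the edgeR fit, no filter (39969 genes) or a stricter one (CPM of 1 in 4 tumours, 16580 genes), robust estimation off, the mean of 33 host endothelial and leukocyte genes as a covariate, only the 8 tumours compared, DESeq2 1.42.0 on the same genes without independent filtering, limma-voom, and each tumour left out in turn. Alternatives added after the results were seen removed smooth trends on GC content and transcript length (mgcv 1.9.3, GC content known for 99.6% of tested genes) or left out pairs of tumours. The overlap of responses was compared with 20 simulated draws of unchanged groups sharing the controls and with the 3 ways of splitting the controls into pairs. The other splits of the tumours of a comparison, 35 for 2 groups and 100 drawn for the interaction, were fitted in the same way.

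The edgeR procedure was tested on simulated data drawn with the fitted means and dispersions of all 16 tumours, with changes put into the GANT61+RITA group. Of 200 changed genes among 20118, it called 13 of 67 changed 1.5-fold (19.4%), 51 of 67 changed 2-fold (76.1%) and 59 of 66 changed 4-fold (89.4%), with 3 false calls. The changed genes were drawn only from genes above a minimum mean level. Noise was drawn for each gene independently, without variation shared across genes of a tumour. Figures were drawn with matplotlib 3.10.9. The controls were untreated, so effects of solvent, gavage and injection cannot be separated from those of the drugs. Mouse reads were not counted separately in the table analysed, and raw reads were not analysed here.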

Results

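RNA was sequenced from 16 subcutaneous xenograft tumours of Rh36, a human embryonal rhabdomyosarcoma cell line grown in nude mice. The tumours form 4 groups of 4. One group was left untreated, and one received RITA, a small molecule named for reactivating the tumour suppressor p53. Another received GANT61, an inhibitor of the GLI transcription factors of the Hedgehog pathway, and the last received both. RITA was injected at 10 mg/kg and GANT61 was given by mouth at 75 mg/kg, daily for 20 days. Total counts per tumour ran from 22799938 to 49192818. In units of mega-counts, group means were 27.2 ± 4.25 in controls, 34.0 ± 11.1 with GANT61, 32.5 ± 7.997 with RITA and 29.3 ± 1.36 with GANT61+RITA (SD, n = 4 each). The controls are described as untreated, so drug, solvent and handling cannot be told apart in any comparison with them. The largest axis of variation, with 24.7% of the variance, set control 2 at −80.2 and the other 15 tumours between −26.8 and 46.6.

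Libraries also differed along 2 further measures. Mitochondrial transcripts made up 11.4 ± 3.50% of counts in controls, 10.7 ± 3.87% with GANT61, 8.59 ± 2.07% with RITA and 6.75 ± 0.46% with GANT61+RITA (SD, n = 4 each). The slope of log2 expression on GC content, per 10 percentage points, was 0.10 ± 0.02 in controls, −0.03 ± 0.10 with GANT61, 0.02 ± 0.06 with RITA and −0.09 ± 0.14 with GANT61+RITA. These means rested on single tumours: that of GANT61 was 0.02 without GANT61 3, −0.05 without GANT61 1 and −0.04 without GANT61 2, that of RITA was −0.01 without RITA 2 and 0.04 without RITA 1, and that of GANT61+RITA was −0.04 without GANT61+RITA 3. All 4 controls had a higher slope than every GANT61 and every GANT61+RITA tumour (exact permutation p = 0.0286, two-sided, and 0.129 after Benjamini-Hochberg adjustment over the 18 comparisons of such measures). This p is the smallest that 4 against 4 tumours can give. Mitochondrial percent was lower in every GANT61+RITA tumour than in every control and every GANT61 tumour, with the same exact p and adjusted p. The mitochondrially encoded gene list tested below draws on these transcripts.

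**Figure D1:**
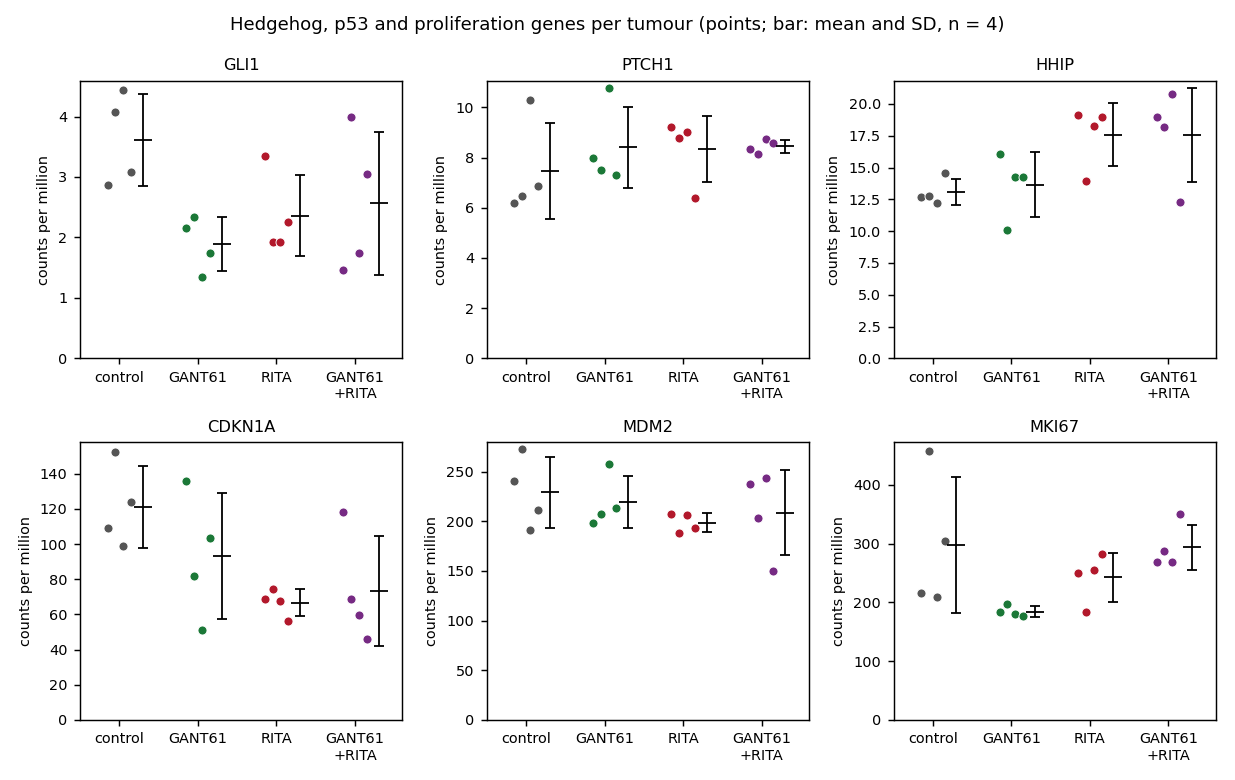
Normalised read counts in CPM, scaled by TMM-adjusted library totals (vertical axes, from 0), of 6 genes in each of the 16 tumours, by treatment group on the horizontal axis, with points for tumours and bars for the mean and SD of 4. GLI1 lay at 3.61 CPM on average in controls and at 1.89 with GANT61, and CDKN1A at 121 in controls and 66.7 with RITA, and none of the 6 genes passed the threshold in any comparison.

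The first comparison asked what RITA alone did to the tumours. The p53 target genes fell: 31 of the 33 members tested were lower than in controls, with a median log2 fold change of −0.37 (adjusted p = 1.48e-12, and adjusted p = 0.462 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687339, GRCh38), was measured at 66.7 ± 7.68 CPM with RITA and 121 ± 23.2 CPM in controls (SD, n = 4 each; log2 −0.86, SE 0.28, adjusted p = 0.844). FDXR, a mitochondrial ferredoxin reductase, AEN, an apoptosis-linked nuclease, DDB2, a DNA damage recognition protein, and SESN2, a stress-responsive sestrin, had the smallest p of this list, at log2 −0.57, −0.57, −1.01 and −0.67. Without control 2 DDB2 stood at −0.54 and AEN at −0.37. MDM2, the ubiquitin ligase that degrades p53 and is itself a p53 target, was at log2 −0.21 (SE 0.14), and TP53 itself at 0.07 (SE 0.11).

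Ribosomal protein and mitochondrially encoded genes fell with RITA as well. All 47 cytosolic ribosomal protein genes were lower, by a median of −0.19 (adjusted p = 7.90e-12, and adjusted p = 0.946 with an estimated correlation). Among them were RPS24 at −0.38, or −0.24 without RITA 4, and RPS27 at −0.28. All 13 mitochondrially encoded genes were lower, by a median of −0.52 (adjusted p = 1.48e-08, and adjusted p = 0.798 with an estimated correlation). Among them were MT-ND2, a subunit of complex I, at −0.64 and MT-CO3, a subunit of cytochrome oxidase, at −0.59, or −0.34 without control 3. Nuclear-encoded genes of oxidative phosphorylation did not pass, with 26 of 34 lower and a median of −0.06 (adjusted p = 0.0524, and adjusted p = 0.954 with an estimated correlation). Mitosis genes fell by a smaller amount, with 25 of 32 lower and a median of −0.12 (adjusted p = 0.00988, and adjusted p = 0.954 with an estimated correlation), and PTTG1, securin, was at −0.38.

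Higher with RITA were skeletal muscle differentiation genes, with 40 of 42 members up and a median of 0.41 (adjusted p = 4.55e-08, and adjusted p = 0.952 with an estimated correlation). ACTA1, skeletal muscle actin, lay at 11.9 ± 4.47 CPM against 5.66 ± 2.54 in controls, and ATP2A1, the calcium pump of fast muscle, at 79.0 ± 20.4 against 48.0 ± 30.9 (SD, n = 4 each). The log2 value of ATP2A1 was 1.21 without control 1 and 0.46 without control 2, beside 0.72 with all tumours. Adult muscle markers chosen for host tissue rose too, with 8 of 8 higher and a median of 0.72 (adjusted p = 0.00295, and adjusted p = 0.946 with an estimated correlation). This list shares genes with the skeletal muscle differentiation list, ACTA1 among them, so its call is not independent of that one. Extracellular matrix and fibroblast genes rose, with 19 of 24 higher and a median of 0.23 (adjusted p = 0.000384, and adjusted p = 0.798 with an estimated correlation). The smallest p in this list were those of LUM, the proteoglycan lumican, at 1.59 (SE 0.44) and FBN1, fibrillin, at 0.44 (SE 0.16). Hypoxia and glycolysis genes rose, with 25 of 30 higher and a median of 0.20 (adjusted p = 0.00170, and adjusted p = 0.954 with an estimated correlation), where CA9, a hypoxia-induced carbonic anhydrase, stood at 0.84 and HK2, hexokinase 2, at 0.67. GLI1, a GLI factor and Hedgehog target, was at log2 −0.61 (SE 0.30), HHIP, a Hedgehog feedback inhibitor, at 0.43 (SE 0.17), PTCH1, the Hedgehog receptor, at 0.17 (SE 0.18), and neither the Hedgehog component list (adjusted p = 0.908) nor the GLI target list (adjusted p = 0.854) passed. Within the latter, FOXF1 lay at −0.71, or −0.38 without control 2, and SNAI2 at 0.28.

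In the test of single genes edgeR called 0 of 20118 for RITA, with 1081 genes at an unadjusted p under 0.05 (489 higher, 592 lower) where chance gives 1006, and DESeq2 and voom called 0 each. Other splits of these 8 tumours gave 103 to 2549 such genes, so 1006 alone does not show the spread by chance. The 1081 became 503 without control 2, 490 without RITA 4, 1922 without control 1 and 1762 without RITA 2. The 5 genes with the smallest p, each at an adjusted p of 0.844, were MT-TW at log2 −0.95, CHDH at −1.49, DSG2 at 0.62, KBTBD11-OT1 (ENSG00000253696) at −1.61, or −0.91 without control 2, and CCDC149 at −0.81. Adjusted over the list alone, 9 genes in 4 lists passed, 6 of them p53 targets, beside NLRC5, APCDD1 and LUM, and the 9 became 0 without control 2 or RITA 4, 3 without RITA 3, 16 without GANT61 3 and 19 without control 1. Without RITA 1 there were 14 such genes but only 1 of the 9, APCDD1, and without control 4 there were 12 with 2 of the 9, NLRC5 and APCDD1. The 6 p53 targets stood at 0.0730 without RITA 1 and at 0.0533 to 0.0630 without control 4, adjusted over the list alone. Without RITA 2 only 4 lists passed in place of 8, and the mitosis and hypoxia lists turned direction with adjusted p of 0.560 and 0.995. The matrix call (adjusted p = 0.0583) and the host muscle call (0.231) also ended without RITA 2, the mitosis call without control 2 (0.975) or control 4 (0.103), the host muscle call without control 2 (0.197) and the hypoxia call without control 1 (0.145).

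The next comparison asked what GANT61 alone did. Hedgehog pathway components and feedback genes fell, with 12 of 16 members lower and a median log2 of −0.21 (adjusted p = 0.00792, and adjusted p = 0.417 with an estimated correlation). GLI1 (ENSG00000111087, chromosome 12, 57460135 to 57472262, GRCh38) was at 1.89 ± 0.44 CPM with GANT61 and 3.61 ± 0.76 in controls, without overlap between the groups (SD, n = 4 each; log2 −0.92, SE 0.31, adjusted p = 0.447). KIF7, a kinesin of the Hedgehog pathway, lay at −0.38, BOC, a Hedgehog co-receptor, at −0.79 and GLI2 at −0.38, while PTCH1 lay at 0.17 (SE 0.18) and HHIP at 0.07 (SE 0.17). Without control 2 BOC stood at −0.43 and GLI2 at −0.25. Of 23 GLI target genes 16 were lower, with a median of −0.16, and this list missed the threshold (adjusted p = 0.0538), with FOXF1 at −0.80, FOXC2 at −1.02 and FOXM1 at −0.56, where FOXF1 stood at −0.47 and FOXC2 at −0.59 without control 2.

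Proliferation genes fell with GANT61. Of the 32 mitosis genes 31 were lower, by a median of −0.38 (adjusted p = 4.32e-14, and adjusted p = 0.658 with an estimated correlation), and of the 32 DNA replication genes 30, by a median of −0.25 (adjusted p = 4.33e-07, and adjusted p = 0.843 with an estimated correlation). MKI67, which encodes the proliferation marker Ki-67 (ENSG00000148773, chromosome 10, 128096659 to 128126385), was at 184 ± 9.08 CPM against 297 ± 116 in controls (SD, n = 4 each; log2 −0.69, SE 0.20, adjusted p = 0.447), and at log2 −0.39 without control 2. KIF20A and PRC1, both of the central spindle, were at −0.67 and −0.50, CCNE1, cyclin E1, at −0.44 and MCM7, of the replicative helicase, at −0.38. p53 target genes fell here also, with 30 of 33 lower and a median of −0.33 (adjusted p = 6.76e-06, and adjusted p = 0.658 with an estimated correlation). Members included AEN at −0.58, PHLDA3, an AKT inhibitor, at −0.86 and XPC, a DNA repair factor, at −0.31, while CDKN1A lay at −0.38 (SE 0.28), MDM2 at −0.06 (SE 0.14) and TP53 at −0.05 (SE 0.11). Without control 2 AEN stood at −0.38 and CDKN1A at −0.24, and CDKN1A at −0.61 without GANT61 1 and −0.17 without GANT61 3.

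All 23 cholesterol synthesis genes tested were lower with GANT61, by a median of −0.47 (adjusted p = 0.000210, and adjusted p = 0.843 with an estimated correlation). Examples were the enzymes LSS at −0.49 and FDPS at −0.37, the latter at −0.23 without control 2. Muscle genes rose: 39 of 42 skeletal muscle differentiation genes were higher, by a median of 0.60 (adjusted p = 4.33e-07, and adjusted p = 0.843 with an estimated correlation). In this list were CAV3, caveolin of muscle, at 0.63, or 0.37 without GANT61 1, and MEF2C, a myogenic transcription factor, at 1.17. The 8 host adult muscle markers tested, some of them also in the skeletal muscle differentiation list, were higher by a median of 0.90 (adjusted p = 0.0166, and adjusted p = 0.843 with an estimated correlation). COX6A2 lay at 1.13.

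For GANT61, edgeR called 0 single genes, with 2051 at an unadjusted p under 0.05 (781 higher, 1270 lower; 844 without control 2, 3187 without control 1), voom called 0 and DESeq2 called 1, an unnamed gene, ENSG00000278834, at log2 0.83 (adjusted p = 0.0290 by DESeq2), chosen after its values were seen. The 5 genes with the smallest p, each at an adjusted p of 0.447, were ATN1 at −0.54, TXLNA at −0.44, ANAPC2, of the anaphase-promoting complex, at −0.45, HNF4G at 0.86 and HOTAIR, a long noncoding RNA, at −1.08. Adjusted over the list alone, 16 genes passed, all mitosis genes, and the 16 became 0 without control 2, control 4, GANT61 3 or GANT61 4, 10 without GANT61 2 and 64 without control 1. Without control 1 edgeR called 1 gene, JAZF1, at log2 −1.43 (adjusted p = 0.0135), also chosen after its values were seen. Without control 2 the host muscle list no longer passed (adjusted p = 0.255), nor did it without GANT61 1 (0.131) or GANT61 4 (0.154), and with GC and length trends removed the Hedgehog component list stood at an adjusted p of 0.0502. With control 2 and GANT61 3 left out together, 682 genes had an unadjusted p under 0.05, 12 lists passed, and the DNA replication (adjusted p = 0.589) and cholesterol (0.243) calls ended.

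**Figure D2:**
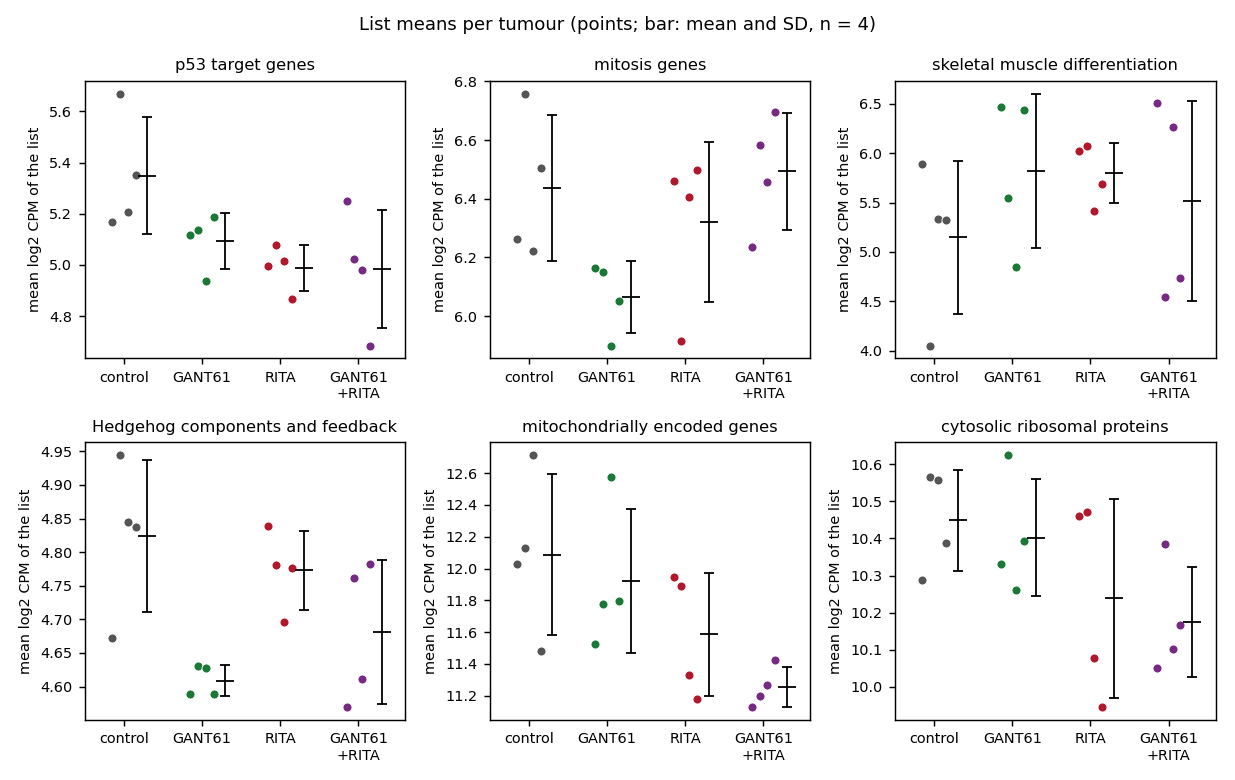
Mean log2 CPM of 6 gene lists in each of the 16 tumours, by treatment group, with points for tumours and bars for the mean and SD of 4. The p53 target list averaged 5.35 in controls and 5.10, 4.99 and 4.98 with GANT61, RITA and GANT61+RITA, and the mitochondrially encoded list 12.09 in controls and 11.25 with GANT61+RITA.

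Both drugs given together were then compared with no treatment. Mitochondrially encoded genes fell, all 13 of them, by a median log2 of −0.90 (adjusted p = 4.83e-09, and adjusted p = 0.945 with an estimated correlation). They are part of the mitochondrial share of counts given above, so this call and that library difference are not independent. MT-CO2 lay at 4571 ± 449 CPM against 8639 ± 2418 in controls (SD, n = 4 each), MT-CO3 at log2 −0.99 and MT-CYB, cytochrome b, at −0.94. All 47 ribosomal protein genes were lower, by a median of −0.28 (adjusted p = 3.40e-08, and adjusted p = 0.945 with an estimated correlation). Named members were RPLP1 at −0.46 and RPL32 at −0.43. p53 target genes fell, with 26 of 33 lower and a median of −0.40 (adjusted p = 1.79e-05, and adjusted p = 0.945 with an estimated correlation). FDXR was at 16.2 ± 2.83 CPM against 27.9 ± 6.34 (SD, n = 4 each; log2 −0.78, SE 0.16, adjusted p = 0.0787), PHLDA3 at −1.02, the death receptor gene TNFRSF10B at −0.67, AEN at −0.61 and CDKN1A at −0.73 (SE 0.28), while TP53 lay at 0.25 (SE 0.11) and MDM2 at −0.13 (SE 0.14).

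HLA class I and antigen presentation genes fell, with all 12 lower and a median of −0.74 (adjusted p = 0.0316, and adjusted p = 0.945 with an estimated correlation). Among its genes were B2M, the HLA light chain, at −0.75, HLA-C at −1.36, or −0.72 without control 4, and NLRC5, an activator of these genes, at −0.74, or −0.34 without control 2. The leukocyte and macrophage markers did not pass, with 16 of 20 lower and a median of −0.54 (adjusted p = 0.131, and adjusted p = 0.945 with an estimated correlation). Extracellular matrix and fibroblast genes rose, with 19 of 24 higher and a median of 0.35 (adjusted p = 0.00895, and adjusted p = 0.945 with an estimated correlation). COL6A3, a collagen VI chain, was at 99.2 ± 34.0 CPM against 44.5 ± 20.7 (SD, n = 4 each), LUM at 1.61 and FBN1 at 0.56. The mitosis, Hedgehog component and GLI target lists did not pass. MKI67 lay at log2 −0.02 (SE 0.20), GLI1 at −0.49 (SE 0.30), PTCH1 at 0.18 (SE 0.18) and HHIP at 0.43 (SE 0.17), where GLI1 stood at −0.29 without GANT61+RITA 1 and −0.78 without GANT61+RITA 2. KIF7 lay at −0.38, PTCH2, a second Hedgehog receptor, at −0.94, the Notch ligand JAG2 at −0.86 and the WNT inhibitor SFRP1 at 0.66.

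Among single genes edgeR called 0 for GANT61+RITA against control, with 4272 at an unadjusted p under 0.05 (2117 higher, 2155 lower) where chance gives 1006 and a smallest adjusted p of 0.0754, voom called 0, and DESeq2 called 1069 (539 higher, 530 lower). In edgeR, other splits of these 8 tumours gave 235 to 3961 genes at an unadjusted p under 0.05, so 1006 alone does not show the spread by chance. The 5 genes with the smallest p, each at an adjusted p of 0.0754, were DNASE1L2 at −1.51, LCAT at −0.90, ZGLP1 at −1.04, MAPK11, a p38 kinase, at −0.80 and NCKAP5L at −0.58. Adjusted over the list alone, 28 genes in 6 lists passed, among them all 13 mitochondrially encoded genes and 9 p53 targets, and the 28 became 15 without control 2 and 50 without control 1. edgeR called 407 genes without GANT61+RITA 4, 272 without GANT61+RITA 2, 76 without RITA 2, 34 without control 4 and 1 without control 1, which was BCL11A at log2 0.96 (adjusted p = 0.0234), chosen after its values were seen. The call of the HLA list ended without control 4 (adjusted p = 0.236) or GANT61+RITA 4 (0.248) and that of the matrix list without control 1 (0.0508) or GANT61+RITA 2 (0.192), while without GANT61+RITA 1 the lists passing went from 5 to 8. With GC and length trends removed 3095 genes had an unadjusted p under 0.05, without GANT61+RITA 3 2672, and with GANT61+RITA 1 and 3 left out together 1729.

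GANT61+RITA was set against RITA to see what the addition of GANT61 changed. Mitosis genes rose, with 29 of 32 higher and a median log2 of 0.17 (adjusted p = 3.26e-05, and adjusted p = 0.975 with an estimated correlation). Members included CENPF, a kinetochore protein, at 0.35, or 0.22 without RITA 2, and KIF11, a spindle kinesin, at 0.36. Mitochondrially encoded genes fell, all 13, by a median of −0.35 (adjusted p = 0.00139, and adjusted p = 0.975 with an estimated correlation). An example was MT-ND5 at −0.71. NRF2 and thioredoxin system genes rose, with 18 of 21 higher and a median of 0.11 (adjusted p = 0.0258, and adjusted p = 0.975 with an estimated correlation). In this list were PGD, an enzyme of the pentose phosphate pathway, at 240 ± 17.9 CPM against 186 ± 13.7 (SD, n = 4 each) and GCLM, of glutathione synthesis, at log2 0.37. GLI1 was at 0.12 (SE 0.30), PTCH1 at 0.01 (SE 0.18), CDKN1A at 0.13 (SE 0.28), MDM2 at 0.07 (SE 0.14), MKI67 at 0.28 (SE 0.20) and TP53 at 0.18 (SE 0.11). MKI67 stood at 0.16 without RITA 2 and 0.18 without GANT61+RITA 4. For skeletal muscle differentiation, which did not pass (adjusted p = 0.0520), the median was −0.01, the mean 0.03 and the direction of the test downward.

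Per gene, edgeR called 0 genes for GANT61+RITA against RITA, with 1019 at an unadjusted p under 0.05 where chance gives 1006, and DESeq2 and voom called 0 each. Other splits of these 8 tumours gave 322 to 2544 such genes. The 1019 became 409 without RITA 2, 552 without GANT61+RITA 3 and 1681 without GANT61+RITA 4. The genes with the smallest p, each at an adjusted p of 0.890, were FAM107B at 0.56, LINC01281 at 1.77, BBOX1-AS1 at 0.68, NCKAP5L at −0.41 and TKTL1 at 3.48, and, adjusted over the list alone, 1 gene passed, HSPA1A of the heat shock list. HSPA1A stood at log2 −2.15, or −0.71 without RITA 2 (0.935 adjusted over the list alone), and it passed in 4 of the 16 fits with a tumour left out. The mitosis call ended without RITA 2 (adjusted p = 0.288) or GANT61+RITA 4 (0.0686), the NRF2 call without RITA 1 (0.0674) or GANT61+RITA 2 (0.526) and the mitochondrial call without RITA 1 (0.0661). The 3 lists passing became 7 without RITA 1, 9 without RITA 3 or RITA 4, 10 without GANT61+RITA 1, 6 without GANT61+RITA 2 and 9 without GANT61+RITA 3.

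Set against GANT61, GANT61+RITA showed what the addition of RITA changed. All 32 mitosis genes were higher, by a median of 0.45 (adjusted p = 8.67e-18, and adjusted p = 0.700 with an estimated correlation), as were 29 of the 32 DNA replication genes, by a median of 0.26 (adjusted p = 1.27e-07, and adjusted p = 0.700 with an estimated correlation). CENPF was at 304 ± 40.5 CPM with both drugs and 183 ± 15.8 with GANT61 (SD, n = 4 each; log2 0.73, SE 0.16, adjusted p = 0.307), MKI67 at log2 0.67 (SE 0.20), CENPE at 0.60, KIF11 at 0.65, RRM1, of ribonucleotide reductase, at 0.44 and MCM6 at 0.44. RAS and ERK feedback genes rose, with 13 of 14 higher and a median of 0.18 (adjusted p = 0.00453, and adjusted p = 0.700 with an estimated correlation). The list held SPRED2 at 0.39 and CCND1, cyclin D1, at 0.36. Matrix genes rose, with 19 of 24 higher and a median of 0.27 (adjusted p = 0.00453, and adjusted p = 0.700 with an estimated correlation). Fibronectin, FN1, lay at 0.49, or 0.27 without GANT61+RITA 2. Cholesterol synthesis genes rose, with 20 of 23 higher and a median of 0.26 (adjusted p = 0.0391, and adjusted p = 0.791 with an estimated correlation). HMGCS1 lay at 0.60.

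Lower with the addition of RITA were all 13 mitochondrially encoded genes, by a median of −0.70 (adjusted p = 3.11e-09, and adjusted p = 0.700 with an estimated correlation). MT-CO2 lay at −0.70. Lower too were 42 of 47 ribosomal protein genes, by a median of −0.21 (adjusted p = 1.21e-07, and adjusted p = 0.747 with an estimated correlation). An example was RPL27 at −0.60. Leukocyte and macrophage markers fell, with 19 of 20 lower and a median of −0.65 (adjusted p = 0.00194, and adjusted p = 0.786 with an estimated correlation). In this list were the integrin gene ITGB2 at −1.43 and CD68, a macrophage marker, at −0.70, which without GANT61 3 stood at −0.63 and −0.28. HLA genes fell, with 11 of 12 lower and a median of −0.55 (adjusted p = 0.0119, and adjusted p = 0.731 with an estimated correlation). B2M lay at −0.48. Muscle differentiation genes fell, with 30 of 42 lower and a median of −0.10 (adjusted p = 0.0208, and adjusted p = 0.791 with an estimated correlation). CDH15, a cadherin of muscle precursors, lay at −0.37, or −0.25 without GANT61+RITA 3. The Hedgehog genes GPR161, GLI3 and HHIP lay at 0.47, 0.42 and 0.36 and GLI1 at 0.43 (SE 0.31), while CDKN1A lay at −0.35 (SE 0.28), FDXR at −0.45, MDM2 at −0.07 (SE 0.14), PTCH1 at 0.01 (SE 0.18) and TP53 at 0.30 (SE 0.11). GLI1 stood at 0.13 without GANT61+RITA 2, and CDKN1A at −0.11 without GANT61 1, −0.54 without GANT61 3, −0.68 without GANT61+RITA 1 and −0.18 without GANT61+RITA 4.

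Per gene, edgeR called 0 genes for GANT61+RITA against GANT61, with 2474 at an unadjusted p under 0.05 (1432 higher, 1042 lower), voom called 0 and DESeq2 called 2, RNASEH1 at log2 0.74 and HNRNPA3 at 0.40 (adjusted p = 0.0264 each by DESeq2), of which HNRNPA3 was chosen after its values were seen. The 5 genes with the smallest p, each at an adjusted p of 0.307, were RNASEH1 at 0.73, the clock gene PER3 at 0.48, the condensin gene NCAPG at 0.56, ASXL2 at 0.53 and CENPF. Adjusted over the list alone, 32 genes in 3 lists passed, among them 19 mitosis and 12 mitochondrially encoded genes, and the 32 became 11 without GANT61 3 and 16 without GANT61+RITA 2, while 19 of the 32 passed without GANT61+RITA 1 and 20 without GANT61+RITA 4. The leukocyte and HLA calls ended without GANT61 3 (adjusted p = 0.141 and 0.117) or GANT61+RITA 4 (0.0916 and 0.191), the muscle call without GANT61 1 (0.632), GANT61 4 (0.358), GANT61+RITA 2 (0.889) or GANT61+RITA 4 (0.577), the cholesterol call without GANT61 2 (0.0671), GANT61 3 (0.185), GANT61+RITA 2 (0.0865) or GANT61+RITA 4 (0.585) and the matrix call without GANT61 2 (0.0931) or GANT61+RITA 2 (0.215). The 10 lists passing became 17 without GANT61+RITA 1 and 6 without GANT61+RITA 4, and with GANT61+RITA 1 and 3 left out together the RAS and ERK call ended (adjusted p = 0.214).

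The single drugs were also set against each other, RITA against GANT61. Mitosis genes were higher with RITA in 30 of 32 cases, by a median of 0.29 (adjusted p = 1.46e-11, and adjusted p = 0.600 with an estimated correlation), and DNA replication genes in 31 of 32, by 0.18 (adjusted p = 1.15e-07, and adjusted p = 0.600 with an estimated correlation). Examples of these lists were the checkpoint kinase gene BUB1B at 0.45, MKI67 at 0.40 (SE 0.20) and CCNE1 at 0.35, the last at 0.21 without GANT61 3. Hedgehog components were higher in 13 of 16 cases, by a median of 0.18 (adjusted p = 0.000232, and adjusted p = 0.0932 with an estimated correlation), and GLI targets in 16 of 23, by 0.15 (adjusted p = 0.000980, and adjusted p = 0.107 with an estimated correlation). Among both lists were HHIP at 17.6 ± 2.45 CPM with RITA against 13.7 ± 2.53 with GANT61 (SD, n = 4 each), GLI3 at log2 0.36, CCND1 at 0.53 and SNAI2 at 0.37. GLI1 lay at 0.31 (SE 0.31) and PTCH1 at 0.00 (SE 0.18). GLI1 stood at 0.18 without GANT61 3 and 0.09 without RITA 1, and HHIP at log2 0.24 without GANT61 2, beside 0.36 with all tumours.

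Cholesterol synthesis genes were higher with RITA than with GANT61 in 20 of 23 cases, by a median of 0.44 (adjusted p = 3.73e-07, and adjusted p = 0.600 with an estimated correlation). LDLR, the LDL receptor, lay at 0.90, or 0.51 without RITA 4. RAS and ERK feedback genes were higher in 13 of 14 cases, by 0.18 (adjusted p = 2.49e-05, and adjusted p = 0.392 with an estimated correlation). DUSP6, an ERK phosphatase, lay at 0.43. Matrix genes rose by a median of 0.25 in 20 of 24 cases, with COL3A1 at 0.55, heat shock genes by 0.18 in 12 of 14, with DNAJB1 at 0.87, and immediate early genes by 0.20 in 16 of 21, with EGR1 at 0.87 (adjusted p = 0.00185, 0.00143 and 0.00829, and adjusted p = 0.600, 0.600 and 0.654 with an estimated correlation). Lower with RITA were 44 of 47 ribosomal protein genes, by a median of −0.11 and with RPL27 at −0.45, and all 13 mitochondrially encoded genes, by −0.31 and with MT-ND6 at −0.78 (adjusted p = 2.19e-08 and 1.87e-05, and adjusted p = 0.600 for both with an estimated correlation). Leukocyte markers were lower in 17 of 20 cases, by −0.41 with CD68 at −0.69, nuclear genes of oxidative phosphorylation in 25 of 34, by −0.07 with NDUFB5 at −0.35, and p53 targets in 22 of 33, by −0.10 with SESN1 at −0.32 and CDKN1A at −0.48 (adjusted p = 0.00829, 0.0159 and 0.0445, and adjusted p = 0.691 for each with an estimated correlation). Without GANT61 3 MT-ND6 stood at −0.43 and CD68 at −0.28, without RITA 2 DNAJB1 at 0.35 and EGR1 at 0.44, and without RITA 1 RPL27 at −0.72 and NDUFB5 at −0.56. COL3A1 stood at 0.37 without GANT61 2 and CDKN1A at −0.24 without GANT61 1. MDM2 lay at −0.14 (SE 0.14) and TP53 at 0.12 (SE 0.11).

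Per gene, edgeR called 0 genes for RITA against GANT61, with 680 at an unadjusted p under 0.05 where chance gives 1006, and DESeq2 and voom called 0 each. Other splits of these 8 tumours gave 180 to 1948 such genes. The 680 became 296 without RITA 4 and 1205 without RITA 1. The genes with the smallest p, each at an adjusted p of 1.00, were DIAPH3 at 0.45, ATN1 at 0.44, LINC00379 at −1.91, BPHL at −0.36 and CD93 at −5.15, and, adjusted over the list alone, CCND1 passed in 2 lists (GLI targets, RAS and ERK feedback), SNAI2 in the GLI target list and NOTCH3 in the NOTCH list. These 3 genes became 0 without control 3, GANT61 2, GANT61 3, GANT61 4 or RITA 4, 1 without control 2, GANT61 1, RITA 3, GANT61+RITA 1 or GANT61+RITA 3, 8 without RITA 1, with 2 of the 3 among them, and 17 without RITA 2, and without control 4 only 1 of the 3 passed. CD93, a receptor of endothelial and myeloid cells, owed its value to GANT61 3 alone, at 30.4 CPM against at most 0.47 in the other 15 tumours, and stood at log2 −0.54 without it. The calls of the leukocyte list (adjusted p = 0.945), the heat shock list (0.181), the mitochondrial list (0.175) and the DNA replication list (0.0747) ended without GANT61 3, and those of the immediate early (0.585), heat shock (0.150) and matrix (0.0770) lists without RITA 2. The p53 call ended without control 4 (0.0529), GANT61 1 (0.150), GANT61 2 (0.178), GANT61 4 (0.178), RITA 1 (0.101) or RITA 4 (0.180), and the oxidative phosphorylation call without GANT61 1 (0.508), GANT61 2 (0.215), GANT61 4 (0.0644) or RITA 3 (0.394). The leukocyte call also ended without GANT61 4 (0.0824), RITA 1 (0.204) or RITA 4 (0.215), the matrix call without GANT61 2 (0.182) and the immediate early call without GANT61 2 (0.137) or RITA 3 (0.0833).

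The interaction asked whether the response to GANT61 differed with and without RITA. All 32 mitosis genes had a positive interaction, with a median log2 of 0.52 (adjusted p = 1.26e-23, and adjusted p = 0.738 with an estimated correlation): against control GANT61 went with a median of −0.38, and against RITA the addition of GANT61 went with 0.17. KIF20A had an interaction of 1.00 (SE 0.28), MKI67 of 0.96 (SE 0.28) and KIF11 of 0.85 (SE 0.24). DNA replication genes had a positive interaction in 32 of 32 cases, by a median of 0.32 and with RRM1 at 0.55, and p53 targets in 30 of 33, by 0.32 and with AEN at 0.54 and CDKN1A at 0.51 (adjusted p = 1.09e-08 and 4.07e-05, and adjusted p = 0.799 for both with an estimated correlation). Muscle differentiation genes had a negative interaction in 41 of 42 cases, by a median of −0.54 and with CAV3 at −0.78, and host adult muscle markers in 8 of 8, by −0.88 and with COX6A2 at −1.66 (adjusted p = 3.78e-10 and 0.000851, and adjusted p = 0.799 for both with an estimated correlation). The muscle lists share genes, so their calls are not independent. GLI1 had an interaction of 1.04 (SE 0.43), PTCH1 of −0.16 (SE 0.26), HHIP of −0.07 (SE 0.24), MDM2 of 0.14 (SE 0.20) and TP53 of 0.23 (SE 0.15). CAV3 stood at −0.52 without GANT61 1, AEN at 0.35 without control 2, and CDKN1A at 0.31 without GANT61 3 and 0.18 without GANT61+RITA 1.

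Per gene, edgeR called 0 genes for the interaction, with 822 at an unadjusted p under 0.05 where chance gives 1006, and DESeq2 and voom called 0 each. The 822 became 389 without control 2, 548 without control 4 and 1595 without control 1. The genes with the smallest p, each at an adjusted p of 0.950, were LINC01281 at 2.40, CCNJ at 0.56, LINC02801 at 1.94, OLIG1 at −1.61 and ITIH5 at 1.503, and 13 mitosis genes passed when adjusted over the list alone. The 13 became 0 without control 2, control 4, GANT61 3, GANT61 4 or GANT61+RITA 4, 1 without RITA 2, which was none of the 13, 4 without RITA 3, 5 without GANT61+RITA 2, 20 without control 1 or control 3 and 24 without GANT61+RITA 1, while 8 of the 13 passed without RITA 1 or GANT61+RITA 3. The 5 lists passing became 8 without control 3, 10 without control 4, RITA 4 or GANT61+RITA 3, and 11 without GANT61+RITA 1. The DNA replication call ended with control 2 and GANT61 3 left out together (adjusted p = 0.0566), and the p53 call with GANT61+RITA 1 and 3 left out together (0.137).

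**Figure D3:**
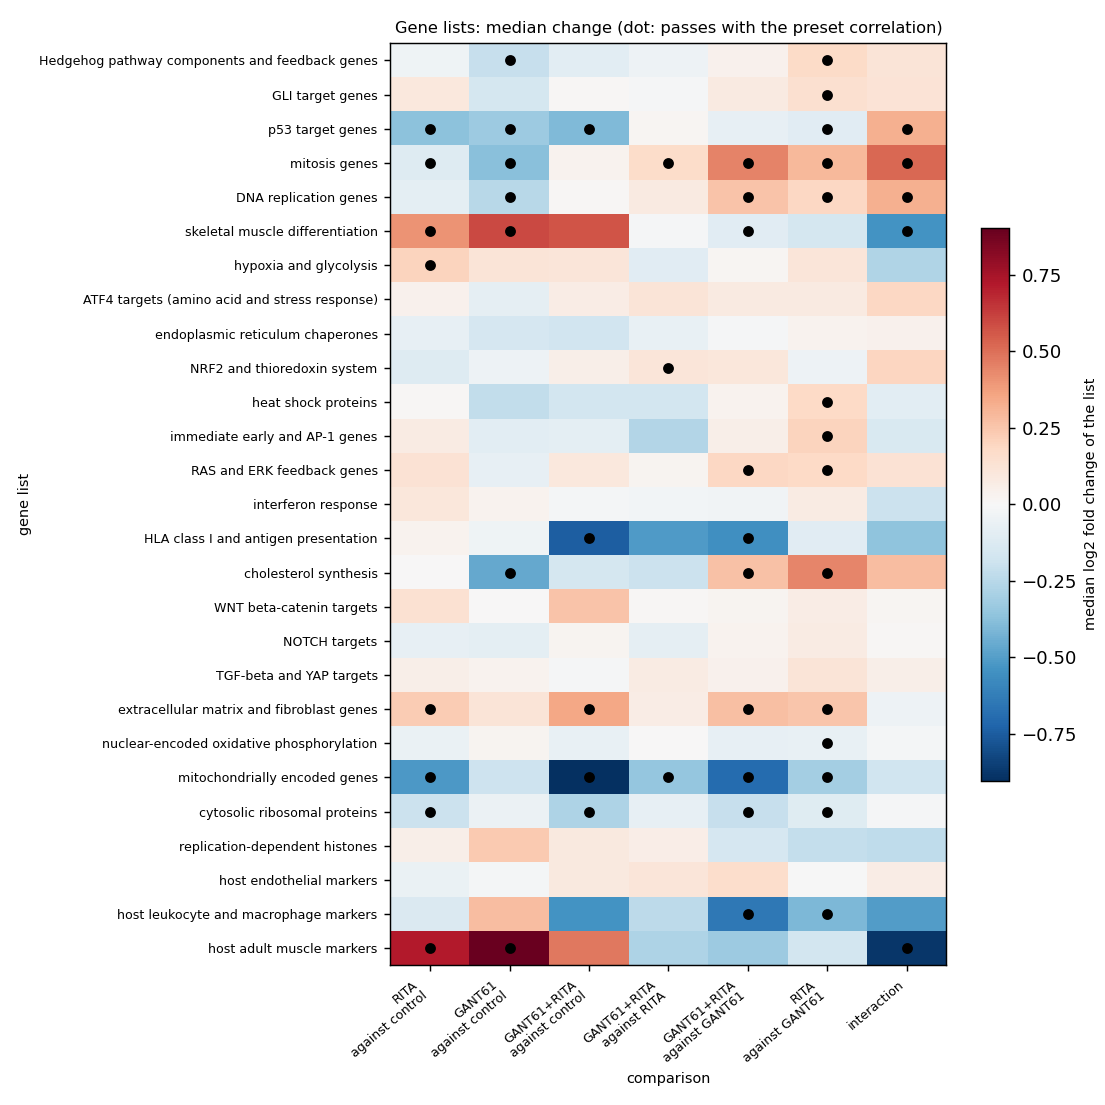
Median log2 fold change (colour) of the 27 gene lists tested (vertical axis) in the 7 comparisons (horizontal axis), with a dot where the list passed with the preset correlation. The p53 target list was lower in each of the 3 treated groups than in controls, at −0.37, −0.33 and −0.40, and the mitosis list went from −0.38 in GANT61 against control to 0.45 in GANT61+RITA against GANT61.

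Over the 7 comparisons 52 list calls were made, and with an estimated correlation, with fry and, for the 6 comparisons of 2 groups, with an exact permutation of list means, none of them passed. The permutation says little here, since its smallest p of 0.0286 cannot pass after adjustment unless many lists reach it. The smallest adjusted p was 0.0932 with an estimated correlation and 0.0835 with fry. Of these calls 29 held with each of the 16 tumours left out in turn, among them the p53 target calls of the 3 treated groups against control. Those fits used the preset correlation again, and the 3 p53 calls share the same controls, so they are not independent of each other. In 27 of the 189 list tests the median, the mean and the direction of the test were not of 1 sign, and none of these 27 passed.

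The 3 responses against control were compared with each other. Across 20118 genes, log2 fold changes of RITA and GANT61 correlated at 0.69, those of RITA and GANT61+RITA at 0.75 and those of GANT61 and GANT61+RITA at 0.66, where groups simulated without effect against the shared controls gave 0.51 each (genes are not independent replicates). With the controls split into separate pairs the means were 0.21, 0.29 and 0.28, and over the 3 splits the correlations ran from 0.03 to 0.32, 0.20 to 0.40 and 0.11 to 0.37. Covariances were 0.0858, 0.109 and 0.109, above the simulated 0.0471, 0.0475 and 0.0474 by 0.0387, 0.0617 and 0.0613. With the controls split into separate pairs the mean covariances were 0.0347, 0.0571 and 0.0576. They ran from 0.0051 to 0.0510, 0.0453 to 0.0735 and 0.0278 to 0.0750. edgeR called 0 genes in both members of any pair and voom 0, while 458, 776 and 1034 genes had an unadjusted p under 0.05 in both with 1 direction, where simulation gave 202, 203 and 199 and independent lists 56.4, 115 and 218. With the controls split into separate pairs the mean counts were 55.8, 182 and 258, with ranges of 31 to 74, 83 to 308 and 168 to 344. DESeq2 called 1 gene in both GANT61 and GANT61+RITA, ENSG00000278834, at log2 0.83 and 0.71, chosen after its values were seen.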

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

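All tests in this part were chosen only after the results were seen, apart from the interaction and the search for outlying tumours.

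The p53 target list was lower in the 12 treated than in the 4 control tumours by −0.33 on the log2 scale (means 5.02 ± 0.15 and 5.35 ± 0.23, SD), with 10 of the 12 below the lowest control (exact permutation p = 0.00330, 0.0890 after adjustment over 27 lists). Removing trends on GC content and length moved the list means of single tumours by −0.04 to 0.08 and left the difference at −0.33, which argues against these trends as the cause. Control 2 alone cannot be excluded: without it the difference was −0.22, 67.2% of the whole (exact permutation p = 0.0396). In 144 of 1820 assignments of 4 tumours as controls some list reached as small a p, so chance is not excluded (real difference −0.33, highest other 0.35 in size). The drugs stay open as an untested explanation, which the design confounds with dosing and handling.

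In GANT61+RITA against control, 1 of 35 splits gave as many genes at an unadjusted p under 0.05, the real one with 4272 (highest other 3961). That is the smallest share that 35 splits can give. It is not adjusted for the 7 comparisons, so chance is not excluded. After removal of GC and length trends the share was 3 of 35 (3095, highest other 3806), so that these trends may be part of the cause. The mean of 33 host endothelial and leukocyte genes as a covariate did not lower the count, which was 4587. Host cells would be mouse cells and the table holds human gene IDs. This covariate is therefore a weak measure of host content and cannot exclude it. With DESeq2, 2 of 35 splits called as many genes (1069, highest other 1232), so chance is not excluded there either. The next split, picked for its count, exchanged 1 control and 1 GANT61+RITA tumour and called 400 genes in edgeR where the real one called 0, which points to a structure among the samples whose cause was not tested.

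GANT61 3 stood apart by leukocyte and blood genes: of 20 leukocyte and macrophage markers 65.0% were highest there, where chance gives 6.25%, which describes the pattern and tests no cause. Host leukocytes and endothelium would be mouse cells and the table holds human gene IDs, so HLA genes and endothelial markers are weak tests. Of 12 HLA class I and antigen presentation genes, which leukocytes also express, 33.3% were highest there, and of 13 endothelial markers 38.5%. Neither more leukocyte cells or reads nor more host tissue of every kind can thus be shown or excluded. The endothelial list mean was close to the highest other (1.21, highest other 1.24), so it does not speak against more host tissue. Matrix genes had 1 of 24 and skeletal muscle genes 0 of 42 highest there, lists whose means of 5.99 and 4.84 would hide a small share. Levels were 30.4 CPM for CD93, 31.2 for THBD, 20.2 for ITGB2 and 33.9 for HBB, against at most 0.47, 1.83, 9.40 and 6.56 in the other 15 tumours (CD93 and THBD both lie at 23045633 to 23086340 of chromosome 20), while PTPRC (6.32), CSF1R (10.2), PECAM1 (7.19) and CDH5 (1.86) were below the highest other tumour (7.07, 12.9, 12.4 and 3.30). No biological explanation beside these was tested.

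For the other comparisons chance is not excluded either. For genes at an unadjusted p under 0.05, as large a count came from 14 of 35 splits for RITA against control (1081, highest other 2549), 6 for GANT61 against control (2051, 2808), 14 for GANT61+RITA against RITA (1019, 2544), 4 for GANT61+RITA against GANT61 (2474, 2758), 15 for RITA against GANT61 (680, 1948) and 54 of 100 for the interaction (822, 3321). For lists passing, as many came from 28 of 35 splits for RITA against control (8, highest other 17), 29 for GANT61 against control (7, 16), 33 for GANT61+RITA against control (5, 18), 35 for GANT61+RITA against RITA (3, 18), 23 for GANT61+RITA against GANT61 (10, 16), 7 for RITA against GANT61 (14, 17) and 94 of 100 for the interaction (5, 16).

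Of 572 groups of 4 values 32 held a tumour far from the others of its group, where chance gives about 1 in 20, or 28.6. Control 1 had a total count of 33.5 mega-counts, and GANT61 3 a GC slope of −0.17. Among list means (log2 CPM), mitosis genes were at 5.92 in RITA 2, ATF4 targets at 4.88 in GANT61 2, immediate early genes at 4.63 in control 4, RAS and ERK feedback genes at 6.37 in RITA 1 and NOTCH targets at 4.23 in GANT61+RITA 2.

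Among genes (CPM), low outlying values were ACTA1 at 2.03 in control 2, PTCH1 at 6.44 in RITA 4, HHIP at 14.01 in RITA 2, XPC at 37.4 in GANT61 4, NCAPG at 50.3 and CENPE at 32.5 in RITA 2, and CCND1 at 318 in GANT61 3. High ones in GANT61 3 were MT-TW at 45.3, MT-ND2 at 5068, HLA-C at 24.6, FN1 at 199.6 and CD93 at 30.4. In other tumours high values were CHDH at 2.16, ANAPC2 at 51.9 and RPL32 at 1117 in GANT61 2, CCDC149 at 1.96 in GANT61+RITA 1, KBTBD11-OT1 at 3.39, DDB2 at 100.5 and TXLNA at 143 in control 2, TXLNA at 101 in RITA 4, HLA-C at 23.1 in RITA 3, SESN1 at 27.4 in RITA 1, and TP53 at 140.4, RRM1 at 184 and FN1 at 351.6 in GANT61+RITA 2.

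For 5 lists the interaction test passed with the preset correlation. Their medians were 0.32 for p53 targets, 0.52 for mitosis, 0.32 for DNA replication, −0.54 for skeletal muscle differentiation and −0.88 for host adult muscle markers. None of them passed with an estimated correlation (smallest adjusted p = 0.738). At least as many lists passed in 94 of 100 groupings, so a differing response to GANT61 is not established. Those groupings exchanged tumours over all 4 groups and are no exact reference for an interaction alone. The muscle lists share genes.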

How the results depend on the processing

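Some alternatives were chosen only after the results were seen. These were removal of GC and length trends and the exact permutation. Others were the fits without control 2 and GANT61 3 or without GANT61+RITA 1 and 3. So were the fits with a tumour left out for list tests, for genes adjusted over a list alone and for GC slopes. The gene lists themselves were written before the data were examined. edgeR called 0 genes in each comparison, and alternatives with other counts were DESeq2, with 1 for GANT61 against control, 1069 for GANT61+RITA against control, 2 for GANT61+RITA against GANT61 and 1 gene shared by 2 responses, and, for GANT61+RITA against control, no filter (61) and host content as a covariate (83). With GANT61+RITA 1 and 3 left out, 2 genes were called against GANT61, RN7SL1 and AL139099.4, which carry 1 value (log2 −2.48, adjusted p = 0.0298) and were chosen after it was seen. With each tumour left out in turn, counts ran from 0 to 1 for GANT61 against control and 0 to 407 for GANT61+RITA against control, and stayed at 0 for the other comparisons. The cause was not tested.

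Lists passing came to 0 in each of the 7 comparisons with an estimated correlation and with fry, and to 0 in the 6 comparisons of 2 groups with the exact permutation, where the smallest p of 0.0286 cannot pass after adjustment unless many lists reach it. With control 2 and GANT61 3 left out 12 passed for GANT61 against control, 8 for GANT61+RITA against control, 5 against RITA and 10 for the interaction. With GANT61+RITA 1 and 3 left out 14 passed for GANT61+RITA against control, 11 against RITA, 18 against GANT61 and 8 for the interaction. With each tumour left out in turn they ran from 4 to 12 for RITA against control, 7 to 10 for GANT61 against control, 4 to 8 for GANT61+RITA against control, 3 to 10 against RITA, 6 to 17 against GANT61, 10 to 15 for RITA against GANT61 and 6 to 11 for the interaction. In RITA against control the mitosis and hypoxia lists turned direction without RITA 2, at adjusted p of 0.560 and 0.995. Their values ran from 8.19e-06 without RITA 4 to 0.975 without control 2 for mitosis, and from 2.68e-13 without RITA 1 to 0.995 without RITA 2 for hypoxia. The cause was not tested.

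Over all alternatives list calls held in 966 cases, ended in 223 and turned in 2. Of these cases 832 left out 1 tumour and kept the preset correlation. All 52 calls ended with an estimated correlation and with fry, and all 47 of the comparisons of 2 groups with the exact permutation. Log2 values of named genes kept their side of the threshold and moved by less than 1 SE in 4963 cases, moved further in 129 and passed the threshold in 58. In 65 of the 5150 cases, over 19 of 185 gene results and none larger than 0.29 with all tumours, the log2 value took the other sign. At 4 tumours per group the test on simulated data found 19.4% of 1.5-fold, 76.1% of 2-fold and 89.4% of 4-fold changes, so that a count of 0 says least about small changes. These shares hold for genes above a minimum mean level and for noise independent between genes. They do not carry over directly to the real tumours and may be too high for them.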

Other observations

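Apart from the planned tests of the lists that passed in no comparison, all tests and genes in this part were chosen only after the results were seen.

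Control 2 had 87 genes at least 2-fold above and 303 at least 2-fold below all 15 other tumours. Among them the p53-linked noncoding RNAs PURPL and MIR34AHG stood at 58.3 and 24.2 CPM, the proteoglycan gene SPOCK1 at 54.1 and the collagen gene COL22A1 at 158, while the scavenger receptor gene MSR1 stood at 0.57, against 25.2 to 124 elsewhere. GANT61 3 had 44 genes above and 14 below all others, RITA 4 had 0 and 67, and GANT61+RITA 3 had 3 and 40.

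In RITA 2 the heat shock gene HSPA1B stood at 172 CPM, and the immediate early genes FOS and EGR3 at 27.02 and 75.8. RITA 3 and control 4 had the highest levels of CD74, the invariant chain of antigen presentation, at 44.6 and 37.5 CPM, and of the peptide transporter gene TAP1, at 4.29 and 3.08. HLA-B stood at 24.4 and 19.9 in these tumours and at 42.9 in GANT61 3.

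Lists that passed in no comparison had their smallest adjusted p at 0.0815 for replication-dependent histones, 0.215 for TGF-beta and YAP targets, 0.235 for NOTCH targets and 0.383 for host endothelial markers (RITA against GANT61), 0.142 for ATF4 targets (GANT61+RITA against GANT61), 0.150 for interferon response (interaction), 0.242 for endoplasmic reticulum chaperones (GANT61 against control) and 0.340 for WNT targets (GANT61+RITA against control).

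Across the 16 tumours 4 relations between list means were tested, with 100000 permutations. The leukocyte and HLA lists were correlated (Pearson r = 0.83, permutation p = 4e-05, adjusted 0.00016, and Spearman rho = 0.81, permutation p = 0.00021, adjusted 0.00084), with r = 0.76 without GANT61 3 and GANT61+RITA 4 (permutation p = 0.00044) and 0.82 within groups. Host leukocytes would be mouse cells, the table holds human gene IDs, and how mouse reads were handled is not given. Whether HLA levels follow leukocyte content therefore cannot be told from this correlation. CD74, in the leukocyte list, is itself a gene of antigen presentation.

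The muscle and mitosis lists had r = −0.51 (permutation p = 0.0423, adjusted 0.0847, and rho = −0.51, permutation p = 0.0435, adjusted 0.0869), −0.49 within groups and −0.24 without control 2 and GANT61+RITA 2, so that the value rests on these tumours and an inverse relation of muscle differentiation and mitosis is not established. Muscle against ribosomal protein lists gave r = −0.25 (permutation p = 0.349), and p53 targets against mitosis gave r = 0.07 (permutation p = 0.815).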
